A study of Mus musculus with 4 samples.

How the data were processed

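Hearts of C57BL/6 mice were frozen, total RNA was taken with Trizol, and libraries were made from 1 ug of RNA after ribosomal RNA removal, per the labels' protocols. The series text describes the RNA as captured with an antibody against ac4C. Strand handling, the region caller, the read counter and any libraries without capture are not given in the sources used here. The submitters' processing notes name FastQC, Salmon and mm10, without versions or roles.

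The deposited table holds whole-number counts per region for the 4 libraries, per the file headers, with no normalisation by the authors that the headers name. It has 652 lines for 558 distinct regions, since a region that overlaps several genes is repeated with the same counts, and the 94 repeats were removed. The authors' log2 fold change is in the same table, per the file headers, and its sign is positive where counts were higher in control. The authors' p-value and q-value of that comparison were deposited beside it, and the tool behind them is not given in the sources used here. Each region carries an overlapped gene (65 overlap none, 22.2% to 24.6% of the counts per library) and a listed gene with its position, and the regions' own positions were not used here. Regions without an overlapped gene have a listed gene, so they were kept in totals and in the region test, with their omission as an alternative. Of 238 nuclear genes checked, 5 had the same start as in the GRCm38 annotation, so the table's coordinates are not those of GRCm38 (mm10). They are printed as the table gives them. Of 459 gene identifiers, 442 were found in that annotation. Low counts were mostly even: of counts below 200, 77.9% to 83.3% per library were even numbers, so counts cannot be taken as independent molecules.

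Libraries were grouped by their labels into 2 control and 2 NAT10 knockout. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples, which can be technical. Replicates were compared before averaging. The Pearson correlation of log2 CPM across regions was 0.984 in both groups. The chi-square per degree of freedom was 4.51 between controls and 16.3 between knockouts (557 degrees of freedom). No pair agreed within the sampling noise of independent counts. Since low counts were mostly even, part of that excess can come from how reads were counted. Regions are not independent replicates.

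The design, tests, gene lists, naming rule and most alternatives were fixed before the data were examined, on the assumption that the table held genes. It held regions, so regions became the unit of the count test, and counts were summed per gene for the gene lists, with genes that share the same regions merged. Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM factors (0.92 and 1.00 in control, 1.18 and 0.92 in knockout), robust dispersion, glmQLFit and glmQLFTest, with Benjamini-Hochberg adjusted p below 0.05. The filter removed 0 of 558 regions and 2 genes, leaving 388 genes or merged genes, of which 11 were higher and 8 lower. The biological coefficient of variation was 12.6% over regions. Intervals from counts cover counting error only and were not used in place of the replicate spread.

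The 46 lists fixed in advance were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2) where at least 5 members were tested, adjusted over 9 lists. Camera with an estimated correlation passed 0 of the 9 lists, and 0 at an unadjusted p below 0.05. Fry, which asks whether a list's genes move one way on balance, passed 0 of the 9 after adjustment and 3 at an unadjusted p below 0.05, with an adjusted p of 0.0801 for the ventricular list. Unequal change among the regions of a gene was tested with edgeR's diffSpliceDGE.

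Named genes were those past the test with a symbol that is not a predicted or clone name, both knockout libraries on the same side of both controls and a CPM of at least 1 in the higher group, up to 12 in each direction. Up to 4 members were named of each list that passed or had at least 2 members past the gene test, and up to 2 of highest level for marker lists that did not pass. The gene that was to be named first, Nat10, is not analysed here.

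The steps were tested on simulated data with the 558 regions and the real library sizes (20 simulations). The region test called 52.4% of regions changed 1.5-fold, 81.8% of those changed 2-fold, 98.6% of those changed 4-fold and 1.45% of unchanged ones. In each simulation 200 regions were changed, against 22 called in the data. More true changes loosen the Benjamini-Hochberg threshold, so these shares can be too high for the data. Camera called the shifted list in 20 of 20 simulations and 1 of 160 unshifted lists. Simulated regions were drawn independently, so these shares do not cover correlated lists such as the ventricular one, with an estimated correlation of 0.545. The test for unequal regions called 124 of 200 genes with a region changed 2-fold and 8 of 1400 others. The simulated genes had more regions each than most of the genes tested. Alternatives were other scalings, filters, tests, thresholds, a replicate block, leaving out each library, and DESeq2 1.42.0. Halved counts, omission of regions without a gene, sums per gene, scaling to 18S and regions as the unit of the lists were added after the data were seen.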

Results

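RNA captured with an antibody against N4-acetylcytidine (ac4C) was sequenced from whole hearts of C57BL/6 mice. N4-acetylcytidine is an RNA base modification, and NAT10 is the acetyltransferase that makes it. All mice carried the treatment label HFD+STZ with exercise in a series on diabetic cardiomyopathy, so neither exercise nor diabetes was compared. The libraries fell into 2 groups, 2 from control and 2 from NAT10 knockout hearts. The deposited table gave whole-number counts for 558 transcribed regions, of which 493 overlapped at least 1 of 456 named genes. The counts summed to 674687 and 686323 in the control libraries and to 920818 and 693922 in the knockout libraries, and these sums cover the listed regions, not whole libraries. Median counts per region were 84 and 92.5 in control and 143.5 and 82 in knockout. A mitochondrial region over mt-Rnr1, mt-Rnr2, mt-Nd1 and mt-Nd2 and the 18S rRNA region Rn18s-rs5 together held 40.7% to 43.8% of the counts per library. Nat10 itself was not analysed here, so the labels had no check from the targeted gene. Libraries without antibody capture were not used here, so a difference in counts can come from RNA abundance, from ac4C or from both.

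The comparison asked which captured RNAs differed between NAT10 knockout and control hearts of these exercised mice. The region over Nppa, which encodes atrial natriuretic peptide, was 4.75-fold lower in knockout, at 426 ± 4.01 against 2026 ± 27.8 normalised counts in control (SD, n = 2; TMM-scaled CPM over the counts in the table). The region over Pdk4, a kinase that inhibits pyruvate dehydrogenase, was 4.52-fold lower, at 54.7 ± 20.3 against 237 ± 15.1 (SD, n = 2). Pam, which encodes the enzyme that amidates peptide hormones, fell from 287 ± 41.6 to 116 ± 0.371 (SD, n = 2). Oxct1, the enzyme that activates ketone bodies for oxidation, rose from 338 ± 44.5 to 611 ± 24.6 (SD, n = 2). The ventricular myosin light chain gene Myl3 rose from 484 ± 0.863 to 771 ± 17.6 (SD, n = 2). An SD of 2 libraries can be small by chance, so values such as 0.371 and 0.863 do not show how precise the counts are.

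By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change of knockout against control was -2.25 ± 0.12 (SE) for Nppa, with an adjusted p of 1.27e-15. It was -2.18 ± 0.24 for Pdk4 (adjusted p = 8.93e-08) and -1.31 ± 0.19 for Pam (adjusted p = 1.29e-05). As the table gives positions, Nppa lies on chromosome 4 from 148085179 to 148086536 and Pdk4 on chromosome 6 from 5483351 to 5496309, on a build not given in the sources used here. The Nppa region also overlaps the antisense gene Gm13054. Several regions were listed with another gene than the overlapped one. Pam was listed with the pseudogene Btf3-ps1, Oxct1 with the antisense gene Gm15632, Chl1 with Gm44436 and Tpm1 with Gm57052. The others were 1 Pink1 region with Mir7019, the region over Hspb6 and Lin37 with Mir9769 and the Atp2a2 region that rose with the pseudogene Gm15846. Strand handling is not given in the sources used here, so the counts of these regions cannot be assigned to 1 transcript with certainty. Of the other regions that fell, 2 overlapped Pink1, the mitophagy kinase, at -0.78 ± 0.22 (adjusted p = 0.0389) and -0.66 ± 0.17 (adjusted p = 0.0197). The latter also overlaps Gm55915. A region of Jph2, a junctophilin that holds the junction of sarcolemma and sarcoplasmic reticulum, fell by 0.74 on the log2 scale (adjusted p = 0.0407). Apoe (-0.68 ± 0.18), 1 region of Dynll2 (-0.65 ± 0.17) and the region over Snx5 and the small nucleolar RNA Snord17 (-0.55 ± 0.14) fell as well, with adjusted p of 0.0197, 0.0203 and 0.0138. The other regions of Dynll2 stood at -0.18 ± 0.16 (adjusted p = 0.578) and -0.30 ± 0.18 (adjusted p = 0.397). Nppa, Pdk4 and Pam passed without any 1 library, while the other 6 named regions that fell each lost the call without at least 1. The first Pink1 region stood at -0.50 without control replicate 2 (adjusted p = 0.321), -0.51 without knockout replicate 2 (adjusted p = 0.362) and -1.22 without knockout replicate 1, and Apoe at -0.45 without control replicate 1 (adjusted p = 0.191). Calls also ended for Jph2 and Dynll2 without control replicate 1, for Snx5 and the other Pink1 region without control replicate 2, for Jph2, Apoe, Dynll2, Snx5 and that Pink1 region without knockout replicate 1, and for the same set without knockout replicate 2 (adjusted p from 0.051 to 0.309).

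Among the regions that rose, Oxct1 gained 0.85 ± 0.14 on the log2 scale (edgeR quasi-likelihood adjusted p = 0.000112) and Chl1, a neural cell adhesion molecule, 0.81 ± 0.16 (adjusted p = 0.00138). The region over Pln, Cep85l and Gm47644 rose from 2960 ± 69.7 to 4811 ± 141 normalised counts (SD, n = 2; 0.70 ± 0.15, adjusted p = 0.00378). Pln encodes phospholamban, the inhibitor of the cardiac calcium pump. Contractile genes rose with it: Myl3 by 0.67 ± 0.13 (adjusted p = 0.000776), Tpm1, a tropomyosin, by 0.65 ± 0.12 (adjusted p = 0.000776) and Myl2, the other ventricular light chain gene, by 0.53 ± 0.12 (adjusted p = 0.00335). Myl2 went from 1105 ± 5.51 to 1601 ± 41.4 normalised counts (SD, n = 2). The table places Myl3 on chromosome 9 from 110597503 to 110598862 and Myl2 on chromosome 5 from 122239046 to 122251535. The region over Hspb6, a small heat shock protein gene, and Lin37 rose by 0.63 ± 0.14, Lbh by 0.55 ± 0.13, and 1 region of Atp2a2, the calcium pump gene, by 0.45 ± 0.12 (adjusted p = 0.00378, 0.0106 and 0.0272). Oxct1, Myl3 and Tpm1 passed without any 1 library, and the other 6 did not. The calls of Pln, Hspb6, Lbh, Myl2 and Atp2a2 ended without control replicate 1, those of Pln, Myl2 and Atp2a2 without control replicate 2, and those of Chl1, Hspb6 and Lbh without knockout replicate 1 (adjusted p from 0.061 to 0.282).

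**Figure D1:**
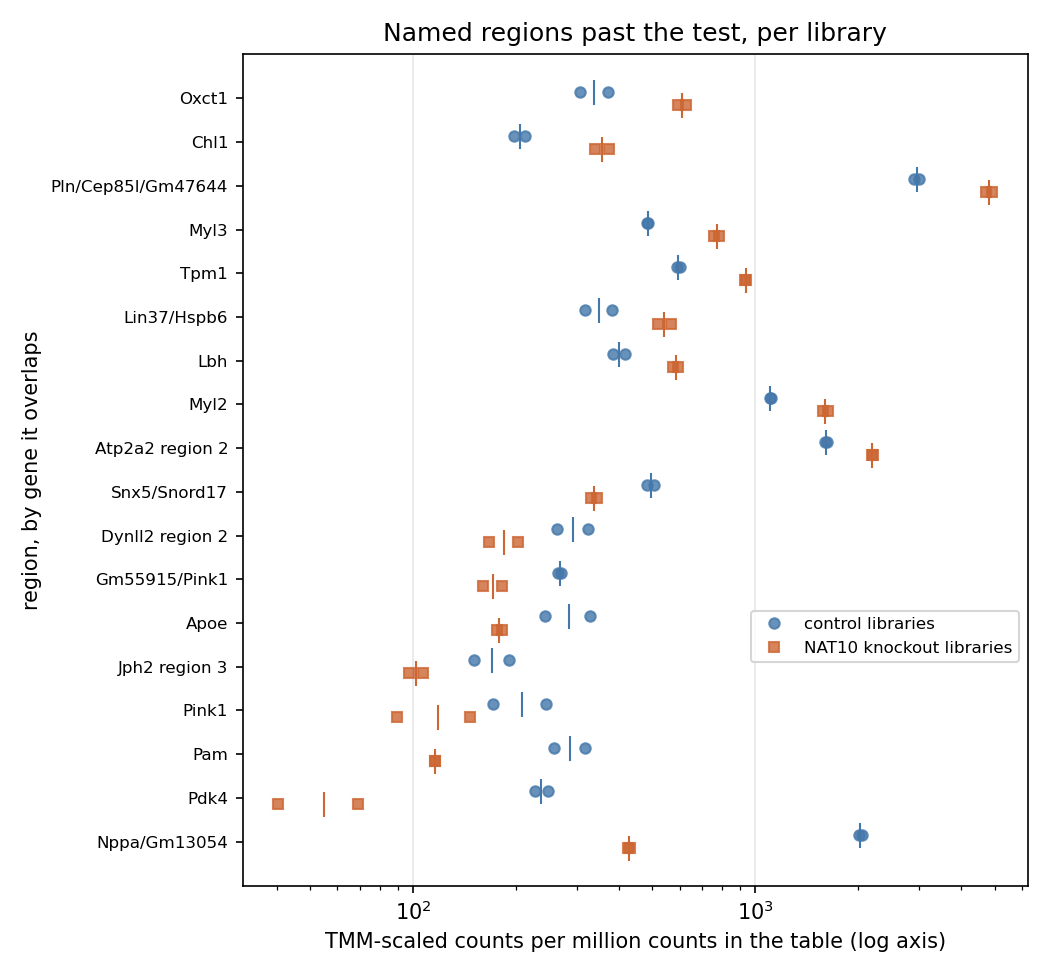
Normalised counts (TMM-scaled CPM over the counts in the table, log axis) of the 18 named regions that passed the test. Circles are the 2 control and squares the 2 NAT10 knockout libraries, and vertical ticks are group means. For Nppa the control mean was 2026 and the knockout mean 426. In each region both knockout libraries lie on the same side of both control libraries, since the naming rule required it.

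In all, 22 of 558 regions passed, 13 higher and 9 lower in knockout. The 4 not named by the rule all rose, and were singled out after their values were seen: 1 overlapped the predicted gene Gm33838, and 3 overlapped no gene and were listed with Gm18604, Coq10a and Gm9075. Both knockout libraries lay on the same side of both control libraries in 265 regions (47.5%), where chance gives 33.3%. The abundant 18S region had a log2 fold change of -0.16 ± 0.36 (edgeR adjusted p = 0.825). Its counts are what remained after ribosomal RNA removal and antibody capture, so it is not a neutral reference for scaling. The count of changed regions was 8 with scaling to the totals alone, 6 with scaling to 18S, 5 with the DESeq2 Wald test, 13 without control replicate 2 and 37 without knockout replicate 2. Of the 18 named regions 5, 3, 5, 12 and 12 passed in these settings, Nppa in each. Myl2 and Myl3 lost their calls with totals alone (adjusted p = 0.0618 each), with the DESeq2 Wald test (0.160 and 0.0747) and, with Pam (0.188), under 18S scaling (0.225 each), and Myl2 also without control replicate 2 (0.0932).

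Of the 9 measured genes typical of ventricular muscle, 5 rose and 4 did not pass when counts were summed per gene (7 rose adjusted over the list alone). All 9 had fitted values above 0, with a median log2 fold change of 0.57. The 5 were Pln (0.73 ± 0.15), Myl3 (0.70 ± 0.14), Lbh (0.57 ± 0.14), Myl2 (0.56 ± 0.13) and Fhl2 (0.43 ± 0.14, edgeR adjusted p = 0.0486), the last named after its value was seen. The Pln counts are those of the region it shares with Cep85l and Gm47644, so they cannot be assigned to Pln alone. That holds for the sarcomere and calcium handling lists too. Myh6, the main myosin heavy chain gene of the mouse heart, stood at 0.01 ± 0.19 over 15 regions. The list passed camera with a preset correlation (adjusted p = 0.00058 over 9 lists), and had an adjusted p = 0.752 with an estimated correlation and 0.0801 with fry. With regions as the unit, where 15 of its 23 regions are of Myh6, its median was 0.06 (adjusted p = 0.0686). Of the atrial list, 2 genes were measured: Nppa fell, and Stard10, whose region also overlaps the antisense gene Gm20476, had -1.38 ± 0.53 (edgeR adjusted p = 0.0968).

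Of the 15 measured genes of the sarcomere list 4 rose (Pln, Myl3, Tpm1 and Myl2, also 4 adjusted over the list alone) and the other 11 did not pass. The median was 0.02 and the camera adjusted p 0.563, and the median moved to 0.16 without control replicate 1, 0.21 with scaling to 18S and -0.07 with upper-quartile factors. Without 1 other library it lay between 0.00415 and 0.07. Titin (Ttn), measured over 22 regions, stood at 0.01 ± 0.16. In the calcium handling list, 1 of 11 genes rose, Pln by its shared region, also 1 adjusted over the list alone. The list had a median of 0.09 and a camera adjusted p of 0.409. That median was 0.20 without control replicate 2, 0.15 without knockout replicate 1, 0.26 with scaling to 18S and -0.01 with upper-quartile factors. Atp2a2 summed over its 7 regions stood at -0.01 ± 0.17.

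Of 12 measured genes of the tricarboxylic acid cycle, 11 had fitted values above 0, with a median of 0.26 (0.16 with upper-quartile factors and 0.44 with scaling to 18S). By edgeR 0 of the 12 passed over all genes, and 3 were higher adjusted over the list alone. These were Got2 (0.46 ± 0.17), Idh3a (0.82 ± 0.31) and Cs, citrate synthase (0.66 ± 0.25), followed by Sdhc at 0.33 ± 0.17. The Cs region also overlaps Gm56959. The list passed camera with a preset correlation (adjusted p = 0.0429), and had an adjusted p = 0.752 with an estimated correlation and 0.0801 with fry. Its call was lost in 10 of 17 settings, among them without control replicate 1 (adjusted p = 0.0648), without control replicate 2 (0.112) and without knockout replicate 2 (0.197).

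In the fatty acid oxidation list 1 of 5 genes fell, Pdk4 (also 1 adjusted over the list alone), while the fatty acid transporter gene Cd36 stood at -0.27 ± 0.14 and Acadm at 0.30 ± 0.18. That list had a median of -0.07 and a camera adjusted p of 0.339, and the sign of the median was not stable: it was -0.15 without control replicate 2, -5e-05 without control replicate 1, 0.03 with totals alone and 0.11 with scaling to 18S. Among 6 glycolysis and glucose genes, Pygm, the muscle glycogen phosphorylase, had -0.51 ± 0.17 (edgeR adjusted p = 0.052) and Pdha1 0.36 ± 0.14 (adjusted p = 0.105). Both passed adjusted over the list alone, 1 in each direction. The list had a median of 0.05, a mean of -0.00049 and a camera adjusted p of 0.976, and its median ranged from -0.11 without knockout replicate 2 to 0.21 with scaling to 18S. The 11 nuclear oxidative phosphorylation genes had a median of 0.05 (camera adjusted p = 0.563), and 0 passed over all genes or adjusted over the list alone. Their median was 0.12 without control replicate 2, 0.00982 without control replicate 1, -0.00017 without knockout replicate 2, -0.05 with upper-quartile factors and 0.22 with scaling to 18S.

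In the autophagy and mitophagy list, Pink1 fell (-0.69 ± 0.14 over 2 regions, edgeR adjusted p = 9.18e-05) and the other 6 genes did not pass, with 1 lower adjusted over the list alone. Its median was -0.14 and its camera adjusted p 0.845, and the median was -0.02 without control replicate 1, -0.06 without knockout replicate 1 and 0.05 with scaling to 18S. Of 9 small noncoding and nuclear RNAs, 8 had fitted values below 0, with a median of -0.22, a camera adjusted p of 0.11, and 0 past the gene test over all genes or adjusted over the list alone. Among these, Malat1 stood at -0.22 ± 0.18 and Rpph1, the RNA of ribonuclease P, at -0.27 ± 0.15. The list passed downward without knockout replicate 2 (median -0.32, adjusted p = 0.0156) and with regions as the unit (median -0.25, adjusted p = 0.0459), and had an adjusted p = 0.752 with an estimated correlation. Its median was -0.11 without knockout replicate 1, -0.14 with scaling to the totals alone and -0.06 with scaling to 18S. Of 4 heat shock genes measured, Hspb6 rose, in a region shared with Lin37 (0.66 ± 0.14, edgeR adjusted p = 0.000156). Cryab stood at 0.31 ± 0.14, Hspb7 at -0.17 ± 0.14 and Hspb8 at -0.23 ± 0.22. Fixed markers of other tissues and cells gave values that did not pass: Lpl (0.35 ± 0.15), Hba-a2 (-0.01 ± 0.52), Ckm (-0.12 ± 0.13), Hopx (0.44 ± 0.18), Rgs5 (0.16 ± 0.25) and Des (-0.30 ± 0.14). Hopx is also in the ventricular list and Des in the sarcomere list, so neither marks another tissue alone. Whether heart muscle itself makes the other RNAs was not tested, so they cannot be read as another tissue or cell either. Abcc9, a member of the smooth muscle and pericyte list named after its value was seen, had the largest fitted value of these. It stood at 1.71 ± 0.57 (edgeR adjusted p = 0.052). The smooth muscle and pericyte list had 1 gene higher adjusted over the list alone. So did the adipocyte, lung and antigen presentation lists (the last by Cd74, 0.65 ± 0.29), where 1 gene was measured and the p is therefore unadjusted. Of the 46 lists, 9 had enough measured genes for camera, 22 had between 1 and 4, and 15 had none in the table.

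**Figure D2:**
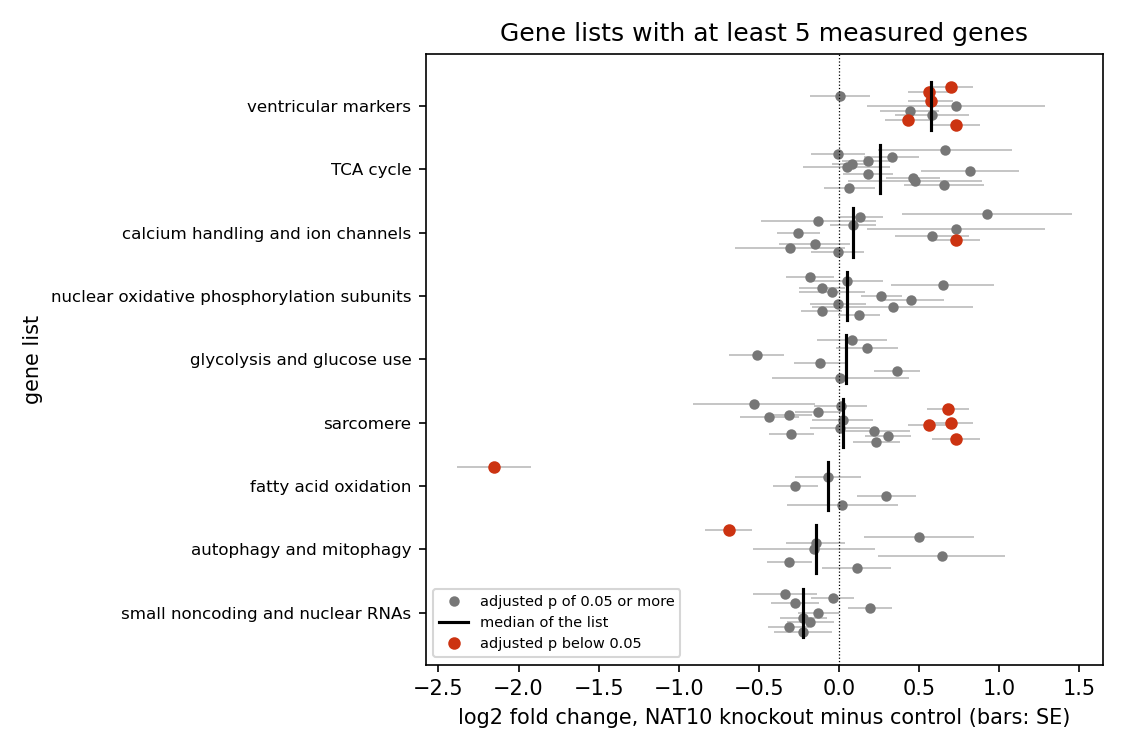
Log2 fold change, NAT10 knockout minus control, of each measured gene (points) in the 9 gene lists with at least 5 tested genes, with the list median as a vertical tick. The ventricular list has a median of 0.57 and the tricarboxylic acid cycle list 0.26. The sarcomere list has a median of 0.02, with genes from -0.53 (Xirp2) to 0.73 (Pln, in a region shared with Cep85l and Gm47644).

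Several genes were covered by more than 1 region. The 15 regions of Myh6 ranged from -0.11 to 0.21 and the 11 regions of Ttn that overlap no other gene from -0.26 to 0.18. The 7 regions of Atp2a2 ranged from -0.30 to 0.45, with 1 higher, and the 4 of Jph2 from -0.74 to 0.12, with 1 lower. Among 49 genes with at least 2 regions, edgeR's test for unequal change of regions called 0 genes by its Simes form and 0 by its gene-wise F form, and 1 gene had an unadjusted Simes p below 0.05. The smallest adjusted p of Atp2a2 in these forms was 0.0696.

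The authors' deposited table also carries their own comparison. Of the 558 regions in the authors' deposited table, 0 had a q-value below 0.05, the smallest being 0.165, and 152 had a p-value below 0.05, of which 135 were higher in knockout. The authors' deposited table gave 429 regions as higher in knockout and 129 as higher in control. Of the 18 named regions, 17 had the same direction in the authors' deposited table as in the edgeR fit. The exception was the Pink1 region listed with Mir7019. Both comparisons use these 4 libraries, so they are not independent. Since most regions are given as higher in knockout, the shared direction of the regions that rose says little. The authors' p-values of the 18 ran from 0.00118 (Pln region) to 0.879 (that Pink1 region), with 0.116 for Pdk4 and 0.108 for Pam.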

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

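Alternatives chosen after seeing the data were halved counts, omission of regions without a gene, sums per gene, scaling to 18S, and regions as the unit of the lists. All 18 named regions kept their direction in the 17 alternatives run on them, and Nppa passed in each of the 17 (log2 fold change -2.28 to -2.05). Across these, 218 values stayed on their side of the threshold and 88 lost the call. The count of changed regions, 22, became 8 with totals only and 6 with scaling to 18S, settings whose median over all regions was 0.15 and 0.22 (0.01 with TMM). It became 5 with the DESeq2 Wald test, 36 at an adjusted p below 0.1 and 3 with at least a 2-fold change, the last by construction. Leaving out 1 library gave 13 (without control replicate 2) to 37 (without knockout replicate 2), with a lone library assumed to vary like the other group. The replicate number as a block left 1 region and 1 list, with 1 residual degree of freedom fewer. Nothing in the labels pairs the libraries, and deviations of same-numbered libraries had a correlation of -0.16 over regions. The count of lists, 2, became 1 with DESeq2 factors, upper-quartile factors, totals only and 18S, 1 to 2 without 1 library, and 0 with an estimated correlation and with fry. It stayed at 2 with a different pair without knockout replicate 2 and with regions as the unit, where small noncoding RNAs passed downward and 1 of the original pair was lost. Lists that did not pass changed the sign of their test in 7 cases. The glycolysis median was 0.15 without control replicate 1, 0.17 without knockout replicate 1 (-0.106 to 0.167 without 1 library), 0.0267 with halved counts, 0.0464 with fry and 0.0571 with regions as the unit. The autophagy median was -0.0218 without control replicate 1 (-0.207 to -0.0218 without 1 library), and the sarcomere median -0.0104 with regions as the unit. Other than by construction, the cause was not tested. The filter removed no region, so its omission tests nothing for regions, and the count of lists stayed at 2 without it.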

Other observations

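The tests on Stard10, on a single scaling factor and on background counts, the count of named regions within 2 SE without either knockout library, and the choice of the regions listed with Mir101c, were made only after the results were seen.

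Of the regions that overlap no gene, 9 were listed with Mir101c, and all 9 had fitted values above 0 in knockout, from 0.31 to 0.94 with a median of 0.51. By edgeR's quasi-likelihood test 0 of the 9 passed (adjusted p from 0.0581 to 0.263), all 9 had an unadjusted p below 0.05, and in 8 both knockout libraries lay on the same side of both controls. They share 1 listed gene, so they cannot be counted as 9 independent observations. The median was 0.36 without knockout replicate 2 and 0.32 without control replicate 2. Of 57 ribosomal protein genes in the fixed list, only 3 were measured: Rplp1 (-0.58 ± 0.21), Rplp0 (-0.55 ± 0.28) and Rpl41 (-0.20 ± 0.37). They were fitted below 0 and did not pass over all genes, with 1 lower adjusted over the list alone.

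Nppa and Pam fell while Myl2 and Myl3 rose, a set that separates atrial from ventricular muscle in the normal heart. Scaling is argued against as the whole cause, since a factor per library moves all regions alike and these moved both ways. The 4 fold changes kept their sign and stayed at least 2.74 SE from 0 over 4 other scalings. That was made likely by choosing regions that passed with TMM. With 18S scaling 3 of the 4 calls ended as the SE grew. Pam went from -1.31 ± 0.19 to -1.10 ± 0.37, Myl2 from 0.53 ± 0.12 to 0.73 ± 0.27 and Myl3 from 0.67 ± 0.13 to 0.87 ± 0.31. All these scalings use the captured counts, so a change common to all regions stays open. The 18S counts also depend on how much ribosomal RNA was removed, so 18S scaling is not a neutral check. Without either knockout library the 4 fold changes stayed at least 4.04 SE from 0. The naming rule, which needs a passed test and both knockout libraries on the same side, made that likely. Of the 18 regions that met the rule, 1 (Pink1) came within 2 SE, at 1.80, against 228 of all 265 regions with the groups apart. The distance therefore cannot decide on 1 knockout library out of place. Both knockout libraries did carry the fall of Nppa, at 429 and 423 normalised counts against 2006 and 2046 in control. Less atrial tissue in the knockout samples was also considered, and the values do not decide it. Stard10, the other atrial gene measured, in a region shared with the antisense gene Gm20476, stood at -1.38 ± 0.53, more than 2 SE below 0. The ventricular median of 0.57 includes Myl2 and Myl3, so it partly restates the set. Lbh, Fhl2 and Hopx, ventricular genes in neither the sarcomere nor the calcium handling list, had a median of 0.44. Of the ventricular genes 4 are also in the sarcomere list, all are heart genes, and Myh6 stood at 0.01. Nppa is also the only measured gene of the fixed cardiac stress and fetal list, where it was lower, not higher, in knockout. A difference in stress response between the groups stays open too, since 1 gene cannot decide on it. An effect of NAT10 loss on these RNAs or on their ac4C stays open, and libraries without capture that would part them were not used here.

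The authors' deposited table gave most regions as higher in knockout, with a Spearman correlation of 0.666 across regions with the present fold changes. A different single scaling factor per library is argued against as the whole difference between both sets, though not as part of it, since the SD of their difference was 0.970 against a median SE of 0.222. Over regions of above-median count, the slope of the authors' fold changes on the present ones was 1.72 (95% bootstrap interval 1.43 to 2.13). A slope stretches both signs alike and gives no excess of one, so whether background counts were subtracted before the ratio stays open. How the authors computed them is not given in the sources used here, and no biological explanation was tested.

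A loss of ac4C at single sites could lower some regions of a gene and leave others, whereas a whole-gene abundance change moves its regions alike. With edgeR's test for unequal change, 0 of 49 genes were called and 1 had an unadjusted p below 0.05. A whole-gene abundance change needs 0 calls, but so does no change at all. Of the 49, only Atp2a2, Jph2 and Dynll2 had a region past the region test, so the others had no called change to compare. In simulated data the same test called 124 of 200 genes with a region changed 2-fold. The simulated genes had more regions each than most of the 49, so that share does not carry over to them. Unequal changes among the regions of a gene therefore stay open, as does a change of ac4C that is equal over a gene.

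Fold changes of each knockout library against a different control library had a mean Spearman correlation of 0.322 across regions (95% bootstrap interval 0.246 to 0.393). It was 0.245 and 0.400 in the 2 ways of splitting the controls. Both values lie outside that interval, which therefore does not measure the spread between libraries, and regions are not independent replicates.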
